A study of Hipposideros armiger and Mus musculus with 20 samples.

How the data were processed

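RNA sequencing of adipose tissue was analysed from 8 libraries of ICR mice and 12 of the great roundleaf bat. Per the labels, total RNA was extracted with a lipid tissue kit and libraries were made by a standard Illumina protocol. The deposited table holds FPKM (fragments per kilobase of transcript, scaled to the reads of the library) for 14871 genes in 20 libraries, and CASAVA 1.8 is the tool named in the submitters' processing notes. The aligner, the counter, the genome build, the reads that set the scale and the way bat reads were assigned to mouse genes are not given in the sources used here. The values were checked to be neither whole counts nor logarithms. Symbols were found for 14723 identifiers, and 148 had none. No table of counts was used here, so counting intervals and floors were not computed.

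Depth was read from the values, on the assumption that low FPKM values of 1 gene are whole multiples of the value of 1 fragment. Among low genes, the ratio to the first library of the species was within 0.5% of a ratio of whole numbers up to 5 at 1 common depth in at least 24.5% of genes in mouse and 42.9% in bat libraries, against at most 4.1% and 2.8% at shifted depths. This gives depths relative to each other, not totals.

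Groups were species, tissue and temperature, each with 1 female and 1 male. Values were taken as log2(FPKM + 1), and genes with at least 1 FPKM in at least 2 libraries of the species were kept (10689 in mouse, 11025 in bat, 9400 in both). A linear model with a mean for each group and a term for sex was fitted to each species, and to all 20 libraries for differences between species, in limma 3.58.1 under R 4.3.3 with an intensity trend. Tests were two-sided, and p-values were adjusted by Benjamini and Hochberg within each comparison, with calls at an adjusted p under 0.05. The spread of each group of 2 was thus taken from all libraries in the fit, moderated across genes. There were 18 comparisons chosen before the data were examined, namely cold in each tissue, its mean per species, the depots, the interactions and sex, and 2 more interactions of bat aWAT added after the data were seen. Coefficients are printed less the median over all genes of the comparison, since in some this moved by over 0.1 with scaling. The p-values, calls and counts are those of the coefficients without this shift. A test of groups of 2 by permutation could not reach the threshold and was not used.

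The genes named were chosen by a rule written before the data were examined. For each cold and depot comparison it takes up to 5 higher and 5 lower genes with the largest change among those called, with both sexes in that direction, a group mean of at least 5 FPKM and a proper symbol. It adds Ucp1, Dio2, Ppargc1a, Cidea, Prdm16, Cpt1b, Fasn, Acly, Lep, Adipoq, Fgf21 and Cirbp, and up to 4 members of each gene list. For means, interactions and sex it takes up to 4 genes each way and Ucp1. Some genes that the rule gives were left out, most of them where a paragraph would have become a list. Elovl3, Cox8b, Scd1 and Rbm3 were among its core genes and were not analysed here.

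The 28 gene lists were also fixed in advance. They cover brown fat and thermogenic genes, electron transport, the TCA cycle, fatty acid oxidation, fatty acid synthesis, triglyceride synthesis and lipolysis, cholesterol synthesis, glycolysis and glucose uptake, white fat cells, general fat cells, extracellular matrix, interferon response, inflammation, cell cycle, chaperones and cold RNA-binding proteins, the clock and the cytosolic ribosome. Lists for other cells cover skeletal muscle, epithelium and mammary gland, B and T lymphocytes, macrophages, endothelium, fibroblasts and progenitors, Schwann cells and nerve, red cells, mesothelium and abdominal organs. Lists with at least 5 measured genes were tested with camera at a correlation of 0.01, adjusted over 122 tests for the cold and 97 for the depots. Camera with an estimated correlation and fry stood beside it, and fry tests whether the genes of a list move one way on balance, not against other genes. Counts of list genes are given over all genes tested and adjusted over the list alone.

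Known changes were simulated in this design with fewer calls than most real comparisons, so real error rates may differ. Of genes changed 2-fold above the low values, 53.2% were recovered for mouse iBAT cold, 55% for mouse sWAT, 60% for bat iBAT, 36.5% for bat sWAT, 54.2% for bat aWAT, 86.8% for the mouse depots and 85.5% for bat iBAT against sWAT. Of those changed 4-fold, 100%, 90.7%, 98.6%, 91.7%, 97.5%, 97.1% and 100% were recovered. Unchanged genes made up 5 of 138, 14 of 153, 6 of 144, 7 of 132, 12 of 155, 9 of 200 and 6 of 193 calls, over 5% in 3 of the 7.

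Alternatives were a pseudocount of 0.1, no filter, median-ratio scaling, quantile normalization, no sex term, the title prefix (same species, temperature and sex) as a random block (statmod 1.5.0), only the libraries of the groups compared, robust eBayes, and leaving out each library in turn. Leaving out the 10 highest genes and rescaling was added after the data were seen. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. No library was left out.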

Results

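RNA was sequenced from fat of ICR mice and of the great roundleaf bat (Hipposideros armiger) held at 30 °C or 10 °C for 7 days. The mouse libraries came from interscapular brown fat (iBAT) and subcutaneous white fat (sWAT), and the bat libraries from iBAT, sWAT and intra-abdominal white fat (aWAT). Each of the 10 groups held 2 libraries, replicate 1 from a female and replicate 2 from a male, which made 8 mouse and 12 bat libraries. Expression was given in FPKM for 14871 genes, which carried mouse gene identifiers in both species. Summed FPKM ran from 263338 to 305098 in mouse and from 294103 to 358510 in bat libraries. Read totals were unknown, but the low values put the depth, relative to the other libraries of the species, between 0.952 and 1.109 in mouse and between 0.624 and 1.079 in bat. In the bat, genes that every cell uses lay near 0, with a median FPKM of 0 for Actb, a cytoskeletal actin, and 0.53 for Eef1a1, a translation factor, while Fabp9, a member of a family of close relatives, had 7253. A bat gene listed near 0 was therefore not taken as absent, and levels were not compared between species.

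Changes are log2 ratios of FPKM + 1 fitted with limma, given ± the standard error, with 2 libraries per group, relative to the median change of all genes tested in that comparison. List medians are relative in the same way. Each pair of FPKM values gives the female library first and the male library second. Replicates differ in sex and so come from different animals, but nothing in the labels says whether tissues that share a title prefix came from the same animal or from separate ones, and p-values measure only the spread between these libraries.

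**Figure D1:**
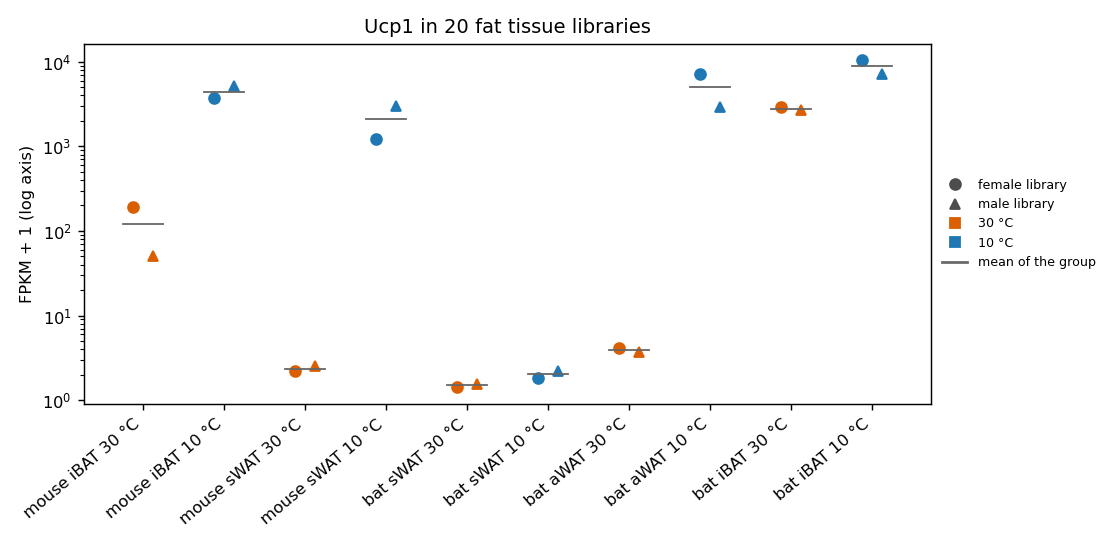
Ucp1 in the 20 libraries, as FPKM + 1 on a log axis, by species, tissue and temperature (circles female, triangles male, orange 30 °C, blue 10 °C, grey line the mean of the group). Cold values lay above warm ones in each of the 10 pairs of the same sex and tissue.

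In brown fat of cold mice, Ucp1 (ENSMUSG00000031710), the uncoupling protein through which brown fat mitochondria give off heat, rose from 192 and 50 FPKM to 3688 and 5119 FPKM (log2 change 5.75 ± 0.71, adjusted p = 0.0132). Genes of fatty acid and triglyceride metabolism were among the largest rises beside it: Acot11, an acyl-CoA thioesterase (5.31 ± 0.14), Acsl5, an acyl-CoA synthetase (4.53 ± 0.14), Agpat2, which makes phosphatidic acid on the way to triglyceride (4.52 ± 0.35), and Acly, which supplies cytosolic acetyl-CoA (4.27 ± 0.35). Dio2, which activates thyroid hormone (3.10 ± 0.26), Clstn3 (3.23 ± 0.46) and the hormone gene Fgf21 (1.05 ± 0.20) also rose. Among the largest falls were Ivns1abp (−3.21 ± 0.17), Apcdd1, an inhibitor of Wnt signalling (−3.14 ± 0.40), and Gadd45b, a stress response gene (−2.97 ± 0.67). Among 10689 genes, limma called 2175, 381 higher and 1794 lower. The median change of all genes was −0.30, and −0.03 with median-ratio scaling, which called 898 higher and 531 lower, while quantile normalization called 467 higher and 357 lower. The count was 2 without any 1 of the 4 iBAT libraries and 1396 without the male 30 °C sWAT library.

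Of 16 fatty acid synthesis genes 12 [13] rose and 1 [1] fell. Of 14 glycolysis and glucose uptake genes 9 [9] rose. Of 18 cholesterol synthesis genes 9 [10] rose and 1 [1] fell (adjusted over the list alone in brackets). Medians were 2.20, 1.59 and 1.32 (camera adjusted p = 1.20e-15, 2.76e-14 and 2.76e-14, and adjusted p = 0.586, 0.378 and 0.586 with an estimated correlation). Beside Acly, these included fatty acid synthase (Fasn, 3.93 ± 0.58), and Pgd (3.86 ± 0.30) and malic enzyme (Me1, 3.69 ± 0.49), which make NADPH. Hexokinase 2 (Hk2, 2.81 ± 0.52), the phosphofructokinases Pfkp (2.71 ± 0.16) and Pfkl (2.33 ± 0.14), and Gpd1, which makes glycerol phosphate (3.12 ± 0.49), were examples. Squalene epoxidase (Sqle) rose from 2.53 and 1.81 FPKM to 15.9 and 20.2 FPKM (2.88 ± 0.30), beside Nsdhl (2.75 ± 0.17), a later enzyme of the pathway. Of 23 triglyceride synthesis and lipolysis genes 5 [5] rose and 3 [3] fell. Of 18 TCA cycle genes 3 [5] rose and 1 [1] fell. Of 24 fatty acid oxidation genes 3 [1] rose. Medians were 0.66, 0.56 and 0.62 (camera adjusted p = 0.000345, 7.67e-06 and 2.67e-06, and adjusted p = 0.753, 0.748 and 0.734 with an estimated correlation). Mogat1, a monoacylglycerol acyltransferase (2.08 ± 0.33), and Pdhb of the pyruvate dehydrogenase complex rose (2.15 ± 0.20) and Idh2, an isocitrate dehydrogenase of mitochondria, fell (−1.41 ± 0.33). Of 48 electron transport chain genes 1 [none] fell. Of 31 brown fat and thermogenic genes 7 [7] rose and 2 [3] fell. Medians were 0.31 and 0.40 (camera adjusted p = 0.00331 and 6.65e-05, and adjusted p = 0.814 and 0.676 with an estimated correlation). For electron transport the median without the shift was 0.01 and the mean −0.01, and the median was −0.10 with quantile normalization. Slc6a8, the creatine transporter, fell (−1.83 ± 0.16).

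Of 26 cytosolic ribosome genes 20 [22] fell. Of 12 fibroblast and progenitor genes 7 [11] fell. Of 14 macrophage genes 5 [8] fell (adjusted over the list alone in brackets). Medians were −0.94, −0.71 and −0.41 (camera adjusted p = 3.29e-06, 0.00176 and 0.0294, and adjusted p = 0.734, 0.734 and 0.748 with an estimated correlation). Rps4x, a protein of the small subunit, was at 67.1 and 41.1 FPKM in the warm and 17.2 and 13.2 FPKM in the cold (−1.44 ± 0.14). Csf1r, the receptor that keeps macrophages alive, was among them (−0.70 ± 0.15). Of 21 extracellular matrix genes 6 [8] fell. Of 13 endothelial genes 4 [4] fell. Of 16 clock genes 1 [1] rose and 3 [5] fell. Of 14 chaperone and cold RNA-binding genes 1 [3] rose and 5 [5] fell. Camera adjusted p = 0.102, 0.336, 0.394 and 0.388 did not pass. In these, Dcn (−1.47 ± 0.22) and Mmp2 (−1.20 ± 0.17) of the matrix, Cldn5, a tight junction protein of vessels (−1.72 ± 0.27), the clock gene Hlf (−0.95 ± 0.22), Cirbp, an RNA-binding protein known to be cold-inducible (−1.30 ± 0.29), and the stress factor Xbp1 (−1.02 ± 0.14) fell, while the chaperone Hsph1 (1.21 ± 0.19) and the clock gene Bhlhe40 (2.21 ± 0.35) rose. Of 21 skeletal muscle genes none [none] passed. This list had a camera adjusted p = 0.128, without a call. Ckm, the creatine kinase of muscle, was at 482 and 405 FPKM in the warm and 0.29 and 194 FPKM in the cold (−4.51 ± 2.35, adjusted p = 0.191). Hba-a2, a haemoglobin gene, was at 82.9 and 7041 FPKM in the warm and 2115 and 1621 FPKM in the cold. Calls ended with median-ratio scaling for Idh2, with quantile normalization for Gadd45b, Hk2, Gpd1, Csf1r, Hlf and Cirbp, without the filter on low values for Gadd45b and Hk2 and without the sex term for Fgf21 and Cela1. Of 35 named genes that were called, 2 passed without any 1 of the 4 iBAT libraries and all but at most 1 of those that the filter left without any 1 of the sWAT libraries.

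Mouse sWAT, white fat at 30 °C, was asked whether it takes on genes of brown fat at 10 °C. Ucp1 rose from 1.19 and 1.53 FPKM to 1229 and 2977 FPKM (10.04 ± 0.71, adjusted p = 0.00714), and other genes typical of brown fat rose with it: Cox7a1, a subunit of cytochrome oxidase (7.60 ± 0.31), the lipid droplet gene Cidea (5.81 ± 0.25), and Cpt1b, which admits fatty acids to mitochondria (5.57 ± 0.28). Acot11 (5.31 ± 0.14), Dio2 (2.82 ± 0.26) and Fgf21 (1.61 ± 0.20) rose as well. Antibody genes fell most, with the kappa constant gene Igkc at 10420 and 1846 FPKM in the warm and 999.7 and 26.9 FPKM in the cold (−4.35 ± 0.96) beside Ighg1 (−5.24 ± 0.60) and Jchain (−4.17 ± 0.90), although immunoglobulin segments are alike and the split of reads between them is uncertain. Of 10689 genes limma called 4440, 851 higher and 3589 lower, around a median of −0.37. Median-ratio scaling moved that median to 0.02 and called 1497 higher and 941 lower, and quantile normalization called 1382 higher and 1453 lower. The count was 28 or 368 without the female or male 30 °C sWAT library and 1312 without the male 10 °C sWAT library, and 2110 with only the libraries of the groups compared.

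Brown fat and thermogenic genes numbered 31, of which 16 [16] rose and none [1] fell. Electron transport chain genes numbered 48, of which 44 [46] rose. TCA cycle genes numbered 18, of which 17 [18] rose. Fatty acid oxidation genes numbered 24, of which 22 [22] rose (adjusted over the list alone in brackets). Medians were 1.61, 1.90, 2.58 and 2.59 (camera adjusted p = 2.40e-13, 5.14e-38, 1.55e-20 and 8.32e-23, and adjusted p = 0.586 for each with an estimated correlation). Examples were Cycs, cytochrome c (2.80 ± 0.20), Uqcrc1 of complex III (2.72 ± 0.21), the TCA enzyme Idh3a (3.48 ± 0.30), Dlat of pyruvate dehydrogenase (3.34 ± 0.23), and Hadhb (3.59 ± 0.43), Acadvl (3.51 ± 0.24) and Acaa2 (3.41 ± 0.29), which break down fatty acids. Fatty acid synthesis genes numbered 16, of which 14 [14] rose. Triglyceride synthesis and lipolysis genes numbered 23, of which 11 [13] rose and none [1] fell. Cholesterol synthesis genes numbered 18, of which 10 [11] rose and 2 [2] fell. Glycolysis and glucose uptake genes numbered 14, of which 13 [14] rose (adjusted over the list alone in brackets). Medians were 2.78, 1.46, 1.40 and 2.22 (camera adjusted p = 7.49e-13, 1.69e-11, 3.92e-08 and 1.20e-15, and adjusted p = 0.586, 0.633, 0.658 and 0.378 with an estimated correlation). Fasn went from 79.4 and 262 FPKM to 1934 and 1140 FPKM (3.72 ± 0.58), beside Thrsp, a lipogenic thyroid hormone target (3.92 ± 0.60), Acacb, an acetyl-CoA carboxylase (3.69 ± 0.17), and Acly (3.28 ± 0.35). Agpat2 (4.51 ± 0.35), Lpin1, a phosphatidate phosphatase (2.72 ± 0.29), Hmgcs1 of the mevalonate pathway (3.00 ± 0.27), Hk2 (2.86 ± 0.52) and the glycerol phosphate dehydrogenases Gpd1 (3.99 ± 0.49) and Gpd2 (3.54 ± 0.12) stood among these. Of 15 general fat cell genes 5 [5] rose and 1 [1] fell (adjusted over the list alone in brackets). A median of 1.19 came with a camera adjusted p = 0.000122, and adjusted p = 0.748 with an estimated correlation. Acsl1, a long-chain acyl-CoA synthetase, was an example (2.19 ± 0.40). Lymphocyte genes fell in the same libraries, and muscle genes were high in the male cold library, where Ckm was at 359.7 FPKM against 3.42 in the female cold library and 8.35 and 1.6 in the warm ones. Hba-a2 was at 60.5 and 996 FPKM in the warm and 1690 and 1141 FPKM in the cold.

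Of 11 T lymphocyte genes 10 [11] fell. Of 12 B lymphocyte genes 7 [12] fell. Of 18 cell cycle genes 18 [18] fell. Cytosolic ribosome genes numbered 26, of which 23 [24] fell (adjusted over the list alone in brackets). Medians were −2.80, −2.87, −1.18 and −0.96 (camera adjusted p = 0.0143, 0.0455, 1.31e-05 and 8.69e-06, and adjusted p = 0.814, 0.814, 0.633 and 0.738 with an estimated correlation). Cd79b of the B cell receptor was at 172 and 166 FPKM in the warm and 66.2 and 0.848 FPKM in the cold, so that the fall was far larger in the male pair. Fcrla of B cells (−2.19 ± 0.59), Cd5 of T cells (−3.18 ± 0.86), Birc5 (−1.74 ± 0.18), Top2a (−1.54 ± 0.27) and Mcm5 (−1.60 ± 0.25), which act in division and replication, and the ribosomal Rpl13a (−1.31 ± 0.31) were examples. Skeletal muscle genes numbered 21, of which 1 [none] rose. Extracellular matrix genes numbered 21, of which 1 [none] fell. Endothelial genes numbered 13, of which 1 [none] rose. Medians were 2.56, 0.58 and 0.62 (camera adjusted p = 2.97e-06, 0.0155 and 0.00327, and adjusted p = 0.771, 0.734 and 0.734 with an estimated correlation). Mb, the oxygen store of muscle, rose (3.89 ± 0.82). Of 17 interferon response genes 9 [10] fell. Of 12 inflammatory genes 6 [6] fell. Macrophage genes numbered 14, of which 5 [5] fell. Camera adjusted p = 0.0621, 0.216 and 0.128 did not pass. Of 11 epithelial and mammary genes none [none] passed. Of 8 Schwann cell and nerve genes 1 [1] rose. Camera adjusted p = 0.601 and 0.285 did not pass. Of the interferon and inflammatory genes, Usp18 (−1.06 ± 0.24), Parp14 (−0.94 ± 0.22), Tnf (−1.46 ± 0.32), Icam1 (−1.27 ± 0.34) and Vcam1 (−1.18 ± 0.17) fell, as did Agt, which encodes angiotensinogen (−1.67 ± 0.32). Calls ended without the sex term for Igkc and Jchain, with a pseudocount of 0.1 for Cd5 and with only the libraries of the groups compared for Fcrla, Cd5, Mb and Cela1. Of 42 named genes that were called, 8 or 28 passed without the female or male 30 °C sWAT library and 38 or 32 of the 41 left by the filter without the female or male 10 °C sWAT library.

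In bat iBAT, which held Ucp1 at 2886 and 2670 FPKM at 30 °C already, the cold raised it to 10405 and 7239 FPKM (1.75 ± 0.33, adjusted p = 0.0387). Larger rises were those of Fabp7, a fatty acid binding protein with close relatives and so uncertain (4.89 ± 0.40), Fetub, a secreted fetuin (3.73 ± 0.18), Fam162b (3.62 ± 0.21), and Etnk2, an ethanolamine kinase (3.07 ± 0.26). Apol7a, from a family of near copies and so uncertain (−4.82 ± 0.35), Cdca7l (−3.50 ± 0.67), Phyhd1 (−2.41 ± 0.39) and S100b, a calcium-binding protein (−2.39 ± 0.42), were among the largest falls. limma called 319 of 11025 genes, 171 higher and 148 lower, with a median of −0.10 over all genes. The median was 0.02 with median-ratio scaling, which called 209 higher and 97 lower, and −0.18 without the 10 highest genes, which called 121 higher and 224 lower. The number called was 149 or 151 without the female or male 10 °C sWAT library, 9 or 30 without the female or male 30 °C iBAT library and 18 or 4 without the female or male 10 °C iBAT library.

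Among 47 electron transport chain genes none [8] rose. Among 18 TCA cycle genes 2 [9] rose (adjusted over the list alone in brackets). Medians were 0.70 and 0.79 (camera adjusted p = 3.90e-12 and 7.67e-07, and adjusted p = 0.676 for each with an estimated correlation). Dlst, a subunit of the oxoglutarate dehydrogenase complex, went from 199 and 282 FPKM to 574 and 622 FPKM (1.43 ± 0.28), and Suclg2, of succinyl-CoA ligase, from 6.32 and 9.15 to 15.8 and 20.3 FPKM (1.24 ± 0.17). Among 21 extracellular matrix genes none [none] passed. Among 22 cytosolic ribosome genes none [none] passed. Among 13 endothelial genes none [none] passed (adjusted over the list alone in brackets). Medians were 0.37, −0.17 and −0.31 (camera adjusted p = 0.000453, 0.037 and 0.0383, and adjusted p = 0.633, 0.814 and 0.783 with an estimated correlation). Col3a1, a fibrillar collagen, had 1.41 ± 0.32 and did not pass. Of the 26 brown fat and thermogenic genes, 2 rose, Ucp1 and the mitochondrial gene Letmd1 (1.30 ± 0.25), and 1, S100b, fell, and 4 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.424). Among 23 fatty acid oxidation genes none [3] rose and none [3] fell. Among 16 fatty acid synthesis genes none [none] passed. General fat cell genes numbered 14, of which 1 [1] rose and 1 [1] fell. Camera adjusted p = 0.285, 0.148 and 0.161 did not pass. Single genes of other lists that changed were Rrm2, which makes deoxynucleotides (2.04 ± 0.32), Myl1, a myosin light chain (2.34 ± 0.40), Slc27a1, a fatty acid transporter (−1.01 ± 0.19), Cebpa, a master regulator of fat cells (−1.25 ± 0.28), and Mcm7, a replication helicase (−1.22 ± 0.27). Calls ended with median-ratio scaling for Dlst, Slc27a1 and Cebpa, with quantile normalization for Ucp1 and Letmd1, without the filter on low values for Ucp1, Cdca7l, Dlst, Letmd1, Myl1, Cebpa and Mcm7, without the sex term for Letmd1, with a pseudocount of 0.1 for Ucp1 and without the 10 highest genes for Dlst. Of 17 named genes that were called, 5 passed without the female or male 30 °C iBAT library, 6 or 4 without the female or male 10 °C iBAT library, 14 to 17 without any 1 of the aWAT libraries and 12 to 14 without any 1 of the sWAT libraries.

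Skeletal muscle genes led the changes in bat sWAT, where Ucp1 stayed low at 0.41 and 0.57 FPKM in the warm and 0.826 and 1.2 FPKM in the cold (0.36 ± 0.33, adjusted p = 0.648). The troponin gene Tnnc1 (6.97 ± 0.38), Tcap of the sarcomere (5.75 ± 0.44), the troponin gene Tnni2 (5.57 ± 0.42) and the myosin light chains Mylpf (5.46 ± 0.42), Myl3 (5.37 ± 0.24) and Myl1 (5.33 ± 0.40) were among the largest rises. Ckm was at 2.67 and 0 FPKM in the warm and 38.5 and 93.9 FPKM in the cold. Apol7a, again uncertain (−3.54 ± 0.35), Khdrbs3, an RNA-binding protein (−1.96 ± 0.34), Acsf2, an acyl-CoA synthetase (−1.85 ± 0.30), Dusp10, a MAP kinase phosphatase (−1.84 ± 0.27), and Osbpl3, an oxysterol-binding protein (−1.69 ± 0.24), fell. In all, limma called 122 of 11025 genes, 112 higher and 10 lower, around a median of 0.07. The count was 69 or 67 without the female or male 30 °C sWAT library and 40 or 10 without the female or male 10 °C sWAT library, and 64 with only the libraries of the groups compared.

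Among 18 skeletal muscle genes 16 [18] rose. Among 14 macrophage genes none [12] rose. Clock genes numbered 15, of which 1 [4] rose. Of 22 cytosolic ribosome genes none [none] passed (adjusted over the list alone in brackets). Medians were 4.33, 0.98, 0.39 and −0.38 (camera adjusted p = 2.16e-41, 7.05e-09, 0.00249 and 9.30e-07, and adjusted p = 0.378, 0.633, 0.658 and 0.676 with an estimated correlation). Macrophage genes with large values that did not pass over all genes were Cd68 (1.48 ± 0.53), the haemoglobin scavenger receptor Cd163 (1.35 ± 0.42) and the complement gene C1qb (1.29 ± 0.35). Ciart, a repressor of the clock (1.54 ± 0.22), and Mbp, the basic protein of myelin (1.68 ± 0.33), rose. Schwann cell and nerve genes numbered 7, of which 1 [2] rose. Epithelial and mammary genes numbered 5, of which none [1] rose. Inflammatory genes numbered 13, of which none [2] rose. Camera adjusted p = 0.0765, 0.115 and 0.158 did not pass. Among 26 brown fat and thermogenic genes none [none] passed. Of 47 electron transport chain genes none [none] passed. Of 23 fatty acid oxidation genes none [none] passed. Of 16 fatty acid synthesis genes none [none] passed. Camera adjusted p = 0.72, 0.257, 0.0888 and 0.115 did not pass. Calls ended with quantile normalization for Mbp, without the filter on low values for Khdrbs3, Acsf2 and Mbp, without the sex term for Khdrbs3, with a pseudocount of 0.1 for Mbp and with only the libraries of the groups compared for Khdrbs3, Dusp10, Osbpl3, Ciart and Mbp. Of 13 named genes that were called, 8 passed without the female or male 30 °C sWAT library, 7 or 4 of the 11 left by the filter without the female or male 10 °C sWAT library, 11 without any 1 of the aWAT libraries and 11 to 12 without any 1 of the iBAT libraries.

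In abdominal fat of the bat, Ucp1 rose from 3.18 and 2.67 FPKM at 30 °C to 7184 and 2939 FPKM at 10 °C (10.33 ± 0.33, adjusted p = 2.34e-06), together with Ppargc1a, the coactivator that drives mitochondrial growth (2.55 ± 0.57), Cidea (2.14 ± 0.50), Cpt1b (2.46 ± 0.23), Ckmt2, a creatine kinase of mitochondria (4.09 ± 0.64), and glycerol kinase (Gk, 3.22 ± 0.34). Chga, a granin of secretory granules (5.35 ± 0.84), rose as well. So did Eef1a2, a translation factor (5.21 ± 0.37), Pmp2 (5.52 ± 0.40) and Fabp7 (4.73 ± 0.40), all uncertain for close relatives. Leptin (Lep), the hormone of white fat cells, fell from 1062 and 3631 FPKM to 93.6 and 1151 FPKM (−2.44 ± 0.58), as did Apol7a, again uncertain (−4.66 ± 0.35), S100b (−3.44 ± 0.42), Angpt4, an angiopoietin (−2.94 ± 0.37), Prrt4 (−2.84 ± 0.25) and Daam2 (−2.62 ± 0.37). limma called 1948 of 11025 genes, 1057 higher and 891 lower, around a median of −0.14. The count was 1155 higher and 606 lower with median-ratio scaling (median −0.02), 861 higher and 1430 lower without the 10 highest genes (median −0.24), 454 without the female 30 °C aWAT library and 426 without the female 10 °C aWAT library, and 1144 with only the libraries of the groups compared.

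Of 26 brown fat and thermogenic genes 13 [13] rose and 1 [1] fell. Electron transport chain genes numbered 47, of which 37 [41] rose and 1 [2] fell. Of 18 TCA cycle genes 17 [18] rose. Fatty acid oxidation genes numbered 23, of which 15 [17] rose and none [1] fell (adjusted over the list alone in brackets). Medians were 1.30, 1.66, 2.10 and 1.48 (camera adjusted p = 1.80e-07, 1.69e-24, 5.41e-16 and 6.31e-13, and adjusted p = 0.191, 0.586, 0.586 and 0.586 with an estimated correlation). Hadha went from 67.6 and 114 FPKM to 1350 and 949 FPKM (3.81 ± 0.27), beside its partner Hadhb (3.57 ± 0.30), Etfdh, which passes electrons from fatty acids to the respiratory chain (3.08 ± 0.24), Cpt2 (2.94 ± 0.36), Dlst (2.59 ± 0.28), Sdhb of complex II (2.40 ± 0.31), Ndufs3 of complex I (2.50 ± 0.29) and Cycs (2.41 ± 0.34). Among 14 glycolysis and glucose uptake genes 4 [5] rose and none [1] fell (adjusted over the list alone in brackets). A median of 0.41 came with a camera adjusted p = 0.037, and adjusted p = 0.676 with an estimated correlation. The 4 were Ldhb, a lactate dehydrogenase (3.65 ± 0.47), Gpd2 (2.90 ± 0.36), Tpi1 (2.00 ± 0.34) and Eno1 (1.90 ± 0.23). Fatty acid synthesis genes numbered 16, of which none [none] passed. Among 21 triglyceride synthesis and lipolysis genes 4 [6] rose and 2 [5] fell. Among 17 cholesterol synthesis genes none [none] passed. Camera adjusted p = 0.0896, 0.826 and 0.97 did not pass. Of 13 white fat cell genes 4 [8] fell. Cytosolic ribosome genes numbered 22, of which 7 [15] fell. Interferon response genes numbered 14, of which 5 [6] fell. Of 13 endothelial genes 4 [4] fell. Medians were −0.64, −0.49, −0.40 and −0.52 (camera adjusted p = 0.00498, 4.65e-05, 0.00498 and 0.00356, and adjusted p = 0.633, 0.734, 0.658 and 0.748 with an estimated correlation). Beside Lep these included Nrip1, a corepressor that holds back brown fat genes (−0.90 ± 0.24), the patterning gene Hoxc8 (−0.67 ± 0.19), the ribosomal Rpl11 (−0.92 ± 0.17), the interferon-induced Isg15 (−1.07 ± 0.20) and Mx1 (−0.91 ± 0.21), and Cldn5 of endothelium (−1.05 ± 0.24). Cebpa (−1.26 ± 0.28), Angptl4, an inhibitor of lipoprotein lipase (−1.32 ± 0.29), and Dpt (−1.26 ± 0.28) fell in lists that were not called. Ckm of muscle was low, at 0.129 and 0 FPKM in the warm and 0 and 0.0345 FPKM in the cold. Eef1a2, also on the muscle list, rose. Of 7 mesothelial genes 2 [2] fell (camera adjusted p = 0.058). Calls ended without the filter on low values for Cidea, without the sex term for Lep, Angptl4 and Dpt, with a pseudocount of 0.1 for Ppargc1a and with only the libraries of the groups compared for Nrip1, Hoxc8 and Dpt. Of 38 named genes that were called, 25 or 32 passed without the female or male 30 °C aWAT library and 24 or 35 without the female or male 10 °C aWAT library.

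**Figure D2:**
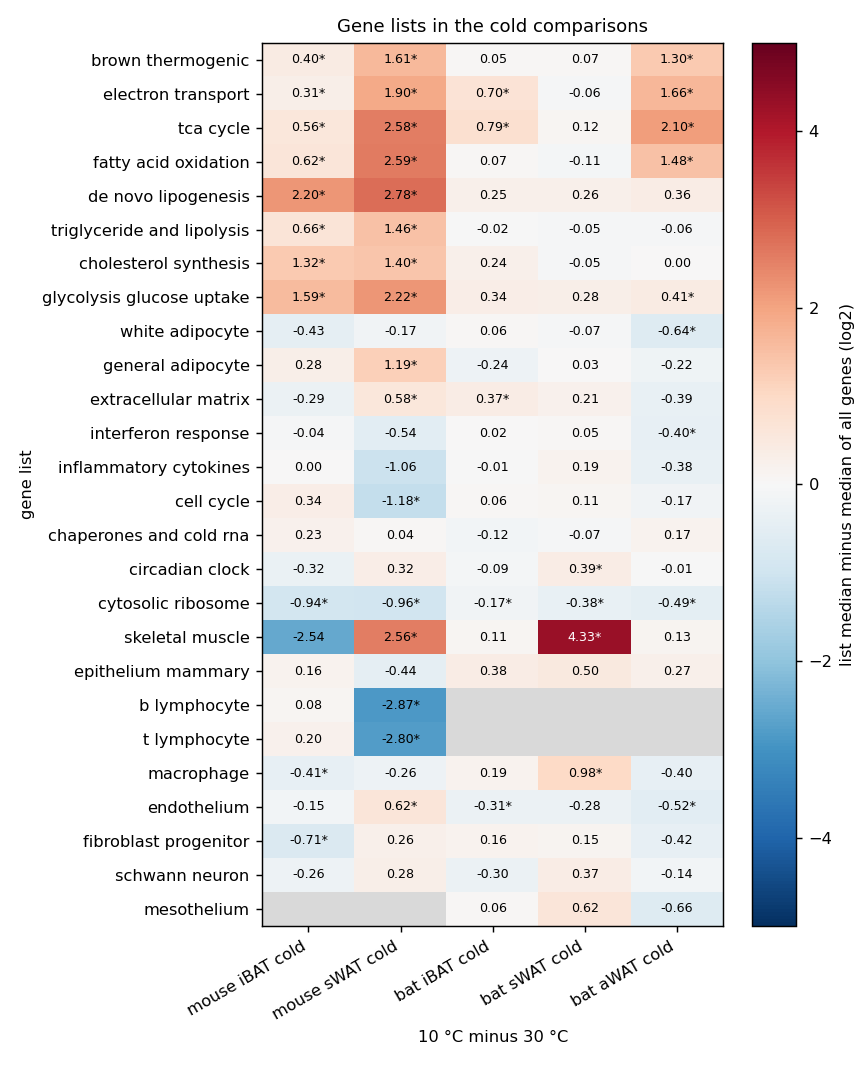
Median log2 change of each gene list at 10 °C minus 30 °C, less the median of all genes, in the 5 cold comparisons (red higher, blue lower, an asterisk for a camera adjusted p below the threshold, grey for lists with fewer than 5 measured genes). By camera at a fixed correlation, the electron transport and TCA cycle lists were above the other genes in all comparisons but bat sWAT, and muscle genes in sWAT of both species. No list was called with an estimated correlation.

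Red cell genes, 3 of them measured, gave no call in any cold comparison over all genes or adjusted over the list alone. Of the abdominal organ genes, 2 measured in mouse and 3 in bat, 1 was called, the elastase gene Cela1, which rose in mouse iBAT (1.45 ± 0.22) and mouse sWAT (1.43 ± 0.22), where adjusted over the list alone 1 rose in iBAT, and 1 rose and 1 fell in sWAT. In the bat only 4 B lymphocyte and 2 T lymphocyte genes could be tested, of which Fcer2a of B cells fell in aWAT (−0.99 ± 0.20). Adjusted over the list alone, 1 B lymphocyte gene rose in iBAT, 1 fell in sWAT, and 1 rose and 1 fell in aWAT, 1 T lymphocyte gene fell in aWAT, and 1 abdominal organ gene rose in bat iBAT.

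**Figure D3:**
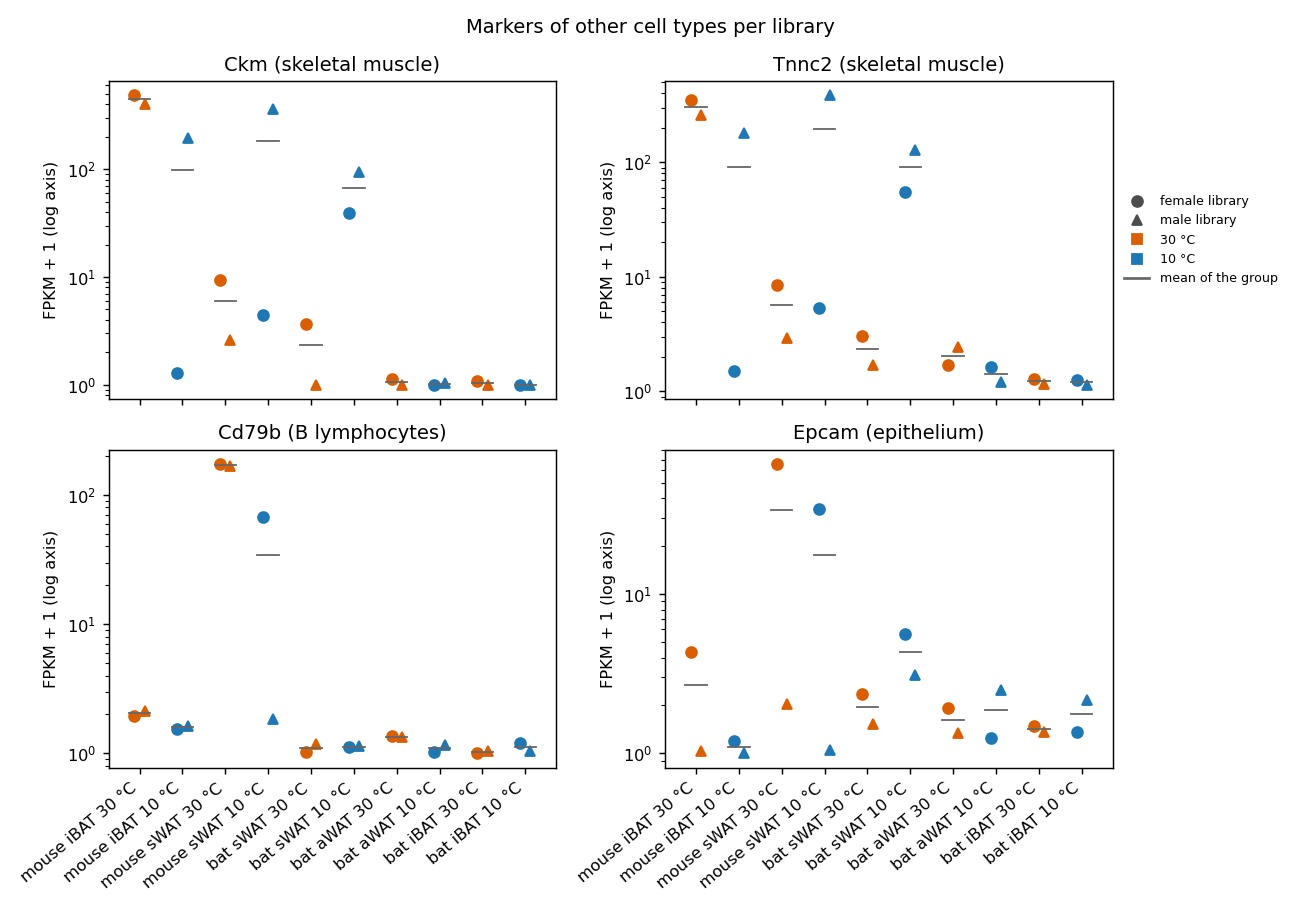
FPKM + 1, on a log axis, of markers of muscle (Ckm, Tnnc2), B lymphocytes (Cd79b) and epithelium (Epcam) in the 20 libraries by group (circles female, triangles male, orange 30 °C, blue 10 °C, grey line the mean of the group). Muscle markers were high in both warm mouse iBAT libraries, the male cold mouse fat libraries and both cold bat sWAT libraries.

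Averaged over the tissues of a species, the cold raised Ucp1 (7.92 ± 0.50), Acot11 (5.34 ± 0.10), Agpat2 (4.55 ± 0.25) and Cox7a1 (4.45 ± 0.22) in mice and lowered Igkc (−3.48 ± 0.68) and Jchain (−3.01 ± 0.64), the antibody genes with their uncertain split. In bats it raised Ucp1 (4.13 ± 0.19), Myl1 (3.23 ± 0.23) and the uncertain Eef1a2 (3.28 ± 0.21) and Fabp7 (3.23 ± 0.23). Ucp1 rose most in aWAT and was not called in sWAT. Myl1, a muscle gene, rose most in sWAT, where admixed muscle stays open. The cold lowered Apol7a (−4.35 ± 0.20), S100b (−2.31 ± 0.24), Cdca7l (−1.89 ± 0.39) and Bloc1s1, a lysosome-related subunit (−1.71 ± 0.39). The mouse mean called 5588 genes, 908 higher and 4680 lower, around a median of −0.36, and 1895 higher and 1254 lower with median-ratio scaling or 1489 higher and 1370 lower with quantile normalization. The count was 3458 or 2501 without the female or male 30 °C iBAT library, 2583 without the female 10 °C iBAT library and 3699 or 3182 without the female or male 30 °C sWAT library. The bat mean called 2467, 1327 higher and 1140 lower, but 1031 higher and 1651 lower without the 10 highest genes, 1010 with the title prefix as a block. It was 1503 without the female 30 °C sWAT library, 1397 or 1538 without the female or male 10 °C sWAT library, 1375 without the female 30 °C aWAT library, 1530 without the female 10 °C aWAT library, 1621 without the female 30 °C iBAT library and 1588 without the female 10 °C iBAT library. Calls ended without the sex term for Igkc and Jchain.

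Of the genes that rose in cold bat aWAT, 904 were also higher in bat iBAT than in sWAT, against 192 if the lists were independent, and 690 were lower in both, against 283. They shared 125 rises and 94 falls with cold bat iBAT, against 16.4 and 12, and 353 rises and 271 falls with cold mouse sWAT, against 75.5 and 248. Cold iBAT of the bat and of the mouse shared 19 rises and 44 falls, against 4.7 and 23.1, and cold sWAT 6 and 2, against 8 and 2.6. Across genes, which are not independent replicates, the correlation of changes with cold bat aWAT was 0.72 for the bat depot difference and 0.37 for cold mouse sWAT, and it was 0.03 between sWAT of the species. These pairs used no libraries in common, but all bat comparisons took their spread from 1 fit. Tissues of 1 title prefix may come from the same animal, so pairs within the bat may not be independent.

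How brown fat differs from white fat was asked over both temperatures. In the mouse, Cox7a1 (4.96 ± 0.22), Cidea (4.35 ± 0.18), Cpt1b (4.17 ± 0.20), Coq8a, a kinase of coenzyme Q synthesis (4.59 ± 0.16), Kng2, a kininogen (4.15 ± 0.25), and Ucp1 (3.81 ± 0.50, adjusted p = 0.0026) were higher in iBAT than in sWAT. Lower in iBAT were genes of immune cells, Ccl5, a chemokine of T cells (−5.24 ± 1.05), Cd52 (−5.02 ± 0.62), Trbc2 of the T cell receptor (−4.89 ± 0.88), Ltb, a lymphotoxin (−4.36 ± 0.87), and Igkc, with its uncertain split (−5.13 ± 0.68), and the posterior patterning gene Hoxc10 (−2.95 ± 0.19). limma called 7439 of 10689 genes, 1060 higher and 6379 lower, around a median of −0.52, which was 0.04 with median-ratio scaling. Scaling turned the balance, with 3064 higher and 2711 lower by median-ratio scaling and 3140 higher and 2582 lower by quantile normalization.

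Brown fat and thermogenic genes numbered 31, of which 17 [17] were higher and 5 [5] lower. Among 48 electron transport chain genes 44 [46] were higher and 1 [1] lower. TCA cycle genes numbered 18, of which 18 [18] were higher (adjusted over the list alone in brackets). Medians were 1.33, 1.83 and 2.36 (camera adjusted p = 9.98e-14, 5.29e-41 and 3.77e-22, and adjusted p = 0.258 for each with an estimated correlation). Among 24 fatty acid oxidation genes 20 [20] were higher and 1 [1] lower. Of 14 glycolysis and glucose uptake genes 12 [12] were higher. Medians were 2.07 and 1.55 (camera adjusted p = 1.87e-20 and 1.72e-12, and adjusted p = 0.258 for each with an estimated correlation). Examples were Slc27a2, a fatty acid transporter (4.04 ± 0.16), Uqcrc1 (2.54 ± 0.15), Acaa2 (3.24 ± 0.20) and Gpd2 (2.79 ± 0.08). Among 16 fatty acid synthesis genes 4 [4] were higher and 3 [2] lower. Of 23 triglyceride synthesis and lipolysis genes 4 [4] were higher and 5 [4] lower. Among 15 general fat cell genes 1 [none] was higher and 1 [none] lower (adjusted over the list alone in brackets). Medians were 0.88, 0.57 and 0.60 (camera adjusted p = 0.00016, 0.00235 and 0.00282, and adjusted p = 0.506, 0.69 and 0.69 with an estimated correlation). The mean of the triglyceride list was −0.08 without the shift. Of 21 skeletal muscle genes 4 [1] were higher. Among 16 clock genes 1 [1] was higher and 2 [1] lower. Medians were 2.68 and 0.33 (camera adjusted p = 3.47e-10 and 0.0289, and adjusted p = 0.506 and 0.282 with an estimated correlation). The clock list had a median of −0.19 without the shift and 0.42 with median-ratio scaling. Mb was higher (3.64 ± 0.58), and Ckm was at 482 and 405 and 0.29 and 194 FPKM in warm and cold iBAT.

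Of 21 extracellular matrix genes 18 [18] were lower. Fibroblast and progenitor genes numbered 12, of which 12 [12] were lower. Of 14 macrophage genes 14 [14] were lower (adjusted over the list alone in brackets). Medians were −1.15, −2.08 and −2.06 (camera adjusted p = 0.000822, 0.000242 and 0.000178, and adjusted p = 0.386, 0.414 and 0.386 with an estimated correlation). Among 17 interferon response genes 16 [16] were lower. Cell cycle genes numbered 18, of which 18 [18] were lower. Among 26 cytosolic ribosome genes 25 [26] were lower (adjusted over the list alone in brackets). Medians were −0.81, −0.85 and −0.92 (camera adjusted p = 0.011, 0.00215 and 0.000388, and adjusted p = 0.768, 0.479 and 0.64 with an estimated correlation). Col1a1, a fibrillar collagen (−2.04 ± 0.11), Mmp2 (−2.67 ± 0.12), Dpt (−2.94 ± 0.14), Lgals3, a galectin of macrophages (−2.67 ± 0.31), Irf7 (−1.75 ± 0.24), Mcm5 (−1.70 ± 0.18) and Rps4x (−1.43 ± 0.10) stood among those. All 12 B lymphocyte and all 11 T lymphocyte genes were lower, also adjusted over the list alone, without a camera call (adjusted p = 0.0649 and 0.0623), among them Cd79b (−4.08 ± 0.95) and Lck (−3.74 ± 0.74). The limit on lymph node tissue holds for these lists too. White fat markers were lower, with Inhbb (−2.24 ± 0.30) and the amino acid transporter Slc7a10 (−2.19 ± 0.36). White fat cell genes numbered 15, of which 11 [11] were lower (adjusted over the list alone in brackets). This list had a camera adjusted p = 0.0623, without a call. All genes named as called for the mouse depots passed without each library in turn.

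In the bat, Ucp1 was higher in iBAT than in sWAT (11.64 ± 0.23, adjusted p = 3.80e-08), and with it Ldhb (6.29 ± 0.33), Serhl (6.17 ± 0.26), the potassium channel gene Kcnk16 (6.11 ± 0.23), Kng2 (6.07 ± 0.25), Ppargc1a (3.84 ± 0.40) and Prdm16, a regulator of brown fat fate (1.96 ± 0.54). Lep was lower, at 39.1 and 259 FPKM in warm iBAT against 3674 and 8635 FPKM in warm sWAT (−6.20 ± 0.41), as were Scd4, a desaturase with close relatives and so uncertain (−6.87 ± 0.92), Gpc3, a glypican (−4.97 ± 0.21), Adipoq, which encodes adiponectin (−2.08 ± 0.26), and the posterior genes Hoxc8 (−4.24 ± 0.14), Hoxc9 (−2.33 ± 0.12) and Hoxc10 (−3.66 ± 0.19). limma called 5504 genes, 2005 higher and 3499 lower, around a median of −0.17. It called 2634 higher and 2698 lower with median-ratio scaling (median −0.01), 2705 higher and 2783 lower with quantile normalization and 1591 higher and 4501 lower without the 10 highest genes.

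Among 26 brown fat and thermogenic genes 19 [19] were higher and none [1] lower. Of 47 electron transport chain genes 44 [44] were higher and 2 [2] lower. Among 18 TCA cycle genes 17 [17] were higher (adjusted over the list alone in brackets). Medians were 2.05, 2.17 and 2.27 (camera adjusted p = 3.08e-10, 2.94e-24 and 9.98e-14, and adjusted p = 0.0394, 0.258 and 0.258 with an estimated correlation). Of 23 fatty acid oxidation genes 20 [20] were higher and 1 [1] lower. Glycolysis and glucose uptake genes numbered 14, of which 8 [8] were higher and 3 [4] lower. Medians were 2.45 and 0.91 (camera adjusted p = 1.37e-14 and 0.00631, and adjusted p = 0.258 and 0.343 with an estimated correlation). Ckmt2 (4.70 ± 0.45), Cpt1b (3.95 ± 0.16), Hadhb (4.86 ± 0.21) and Atp5b of ATP synthase (3.08 ± 0.22) were examples. Among 13 white fat cell genes 10 [10] were lower. Extracellular matrix genes numbered 21, of which 18 [18] were lower. Macrophage genes numbered 14, of which 14 [14] were lower. Among 12 fibroblast and progenitor genes 8 [9] were lower. Medians were −0.69, −2.39, −1.70 and −1.46 (camera adjusted p = 0.00279, 1.06e-07, 3.09e-06 and 0.000539, and adjusted p = 0.282, 0.258, 0.414 and 0.405 with an estimated correlation). Skeletal muscle genes numbered 18, of which 1 [1] was higher and 17 [17] lower, with admixed muscle in cold sWAT open. A median of −2.15 came with a camera adjusted p = 8.49e-07, and adjusted p = 0.476 with an estimated correlation. Col6a1 (−3.06 ± 0.14), Mmp2 (−2.97 ± 0.26), Lgals3 (−3.70 ± 0.18), Dpt (−3.82 ± 0.20), Pi16 of fibroblast progenitors (−2.62 ± 0.21) and Mylpf (−3.49 ± 0.30) stood among the lower genes. Of 24 named genes that were called, 23 to 24 passed without any 1 of the iBAT libraries and 23 to 24 without any 1 of the sWAT libraries.

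Averaged over both temperatures, bat iBAT and aWAT differed in oxidative and mesothelial genes. Ucp1 (5.34 ± 0.23, adjusted p = 1.90e-05), Kng2 (4.50 ± 0.25), Etnppl (3.48 ± 0.19), Enpp6 (3.48 ± 0.24) and Ckmt2 (3.04 ± 0.45) were higher in iBAT, Ucp1 mostly at 30 °C (cold effects 8.55 apart as fitted). Lower in iBAT were the mesothelial genes Upk3b (−4.25 ± 0.25), Upk1b (−3.66 ± 0.25), Msln (−3.65 ± 0.30) and Wt1 (−2.60 ± 0.14), together with Dapl1 (−5.53 ± 0.42), Mgp, an inhibitor of calcification (−3.75 ± 0.29), Hoxc8 (−3.56 ± 0.14) and Lep (−3.50 ± 0.41). limma called 2638 genes, 803 higher and 1835 lower, around a median of −0.14, and 1230 higher and 1142 lower with median-ratio scaling or 1184 higher and 1238 lower with quantile normalization. The count was 1465 without the female 30 °C aWAT library, 1472 without the male 10 °C aWAT library, 1723 without the male 30 °C iBAT library and 1668 without the male 10 °C iBAT library.

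Of 26 brown fat and thermogenic genes 12 [13] were higher. Electron transport chain genes numbered 47, of which 36 [41] were higher and 2 [2] lower. Of 18 TCA cycle genes 16 [17] were higher and none [1] lower. Fatty acid oxidation genes numbered 23, of which 17 [17] were higher and 1 [1] lower (adjusted over the list alone in brackets). Medians were 0.84, 1.04, 1.21 and 1.22 (camera adjusted p = 6.92e-10, 4.98e-24, 9.98e-14 and 7.94e-16, and adjusted p = 0.0394, 0.258, 0.258 and 0.258 with an estimated correlation). Among 14 glycolysis and glucose uptake genes 4 [6] were higher and 2 [2] lower. Of 7 mesothelial genes 6 [7] were lower. Of 13 white fat cell genes 9 [11] were lower. Among 21 extracellular matrix genes 13 [16] were lower. Medians were 0.64, −2.89, −1.49 and −0.89 (camera adjusted p = 0.00138, 1.39e-07, 5.65e-06 and 3.43e-05, and adjusted p = 0.258 for each with an estimated correlation). Among 14 macrophage genes none [1] were higher and 11 [12] lower. Of 12 fibroblast and progenitor genes 7 [10] were lower. Of 22 cytosolic ribosome genes 12 [18] were lower. Medians were −0.97, −0.85 and −0.45 (camera adjusted p = 0.000221, 0.000226 and 3.27e-05, and adjusted p = 0.506, 0.386 and 0.506 with an estimated correlation). Acadm, a fatty acid dehydrogenase (2.63 ± 0.17), Timp1, an inhibitor of matrix proteases (−1.62 ± 0.16), Csf1r (−1.39 ± 0.19) and Dpt (−1.99 ± 0.20) were examples. All genes named as called between iBAT and aWAT passed without each library in turn.

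Averaged over both temperatures, bat aWAT held more Ucp1 than sWAT (6.28 ± 0.23, adjusted p = 7.94e-06), mostly at 10 °C (cold effects 9.77 apart as fitted). It also had more Ppargc1a (2.48 ± 0.40), Adrb3 (1.96 ± 0.40), Ldhb (3.85 ± 0.33), Dapl1 (4.98 ± 0.42), Kcnk16 (4.16 ± 0.23) and Msln (3.24 ± 0.30). Less abundant in aWAT were Scd4, again uncertain (−4.16 ± 0.92), Gpnmb of lipid-laden macrophages (−3.95 ± 0.31), the muscle genes Tnnc1 (−3.91 ± 0.27) and Mylpf (−3.80 ± 0.30), the collagens Col1a1 (−2.13 ± 0.24) and Col1a2 (−2.19 ± 0.22), and Hoxc10 (−1.90 ± 0.19). Muscle genes rose in the cold sWAT libraries (Tnnc1 7.04 as fitted), where admixed muscle stays open, so they may not mark the depot. limma called 1883 genes, 1052 higher and 831 lower, and 799 higher and 1283 lower without the 10 highest genes, which moved the median of all genes from 0.00 to −0.11. The count was 1017 or 1094 without the female or male 10 °C sWAT library, 1039 without the male 30 °C aWAT library and 1208 without the female 10 °C aWAT library.

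Brown fat and thermogenic genes numbered 26, of which 14 [16] were higher. Among 47 electron transport chain genes 42 [43] were higher. TCA cycle genes numbered 18, of which 15 [18] were higher. Among 23 fatty acid oxidation genes 19 [20] were higher (adjusted over the list alone in brackets). Medians were 1.27, 1.08, 1.09 and 1.13 (camera adjusted p = 7.64e-08, 3.09e-23, 1.15e-12 and 1.64e-14, and adjusted p = 0.0471, 0.258, 0.258 and 0.258 with an estimated correlation). The cold rise of these lists in aWAT enters the average, and no contrast of warm libraries alone was run. Mesothelial genes numbered 7, of which 6 [6] were higher. Cytosolic ribosome genes numbered 22, of which none [none] differed. Of 21 extracellular matrix genes 17 [17] were lower. Among 18 skeletal muscle genes 1 [1] was higher and 17 [17] lower. Medians were 3.06, 0.24, −1.02 and −2.28 (camera adjusted p = 2.71e-07, 0.012, 1.11e-11 and 3.50e-16, and adjusted p = 0.258, 0.738, 0.258 and 0.258 with an estimated correlation). Of 14 macrophage genes 5 [6] were lower. Endothelial genes numbered 13, of which 2 [2] were lower. Fibroblast and progenitor genes numbered 12, of which 1 [1] was higher and 6 [7] lower. Among 13 inflammatory genes 2 [2] were lower. Medians were −0.62, −0.39, −0.60 and −0.40 (camera adjusted p = 7.66e-06, 0.00322, 0.00235 and 0.0455, and adjusted p = 0.439, 0.576, 0.468 and 0.752 with an estimated correlation). Hadhb (2.32 ± 0.21), Upk3b (3.06 ± 0.25), Mmp2 (−2.06 ± 0.26), Lgals3 (−2.73 ± 0.18) and Plvap of fenestrated vessels (−1.17 ± 0.13) were examples. Of 19 named genes that were called, all but at most 1 of those that the filter left passed without any 1 of the sWAT libraries.

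Interaction contrasts tested whether these effects differ between depots or species. The mouse cold effect differed between iBAT and sWAT in 6 genes, with Acsl5 rising more in iBAT (2.85 ± 0.20) and Cox7a1 (−6.34 ± 0.43), Cidea (−5.29 ± 0.36) and Cpt1b (−5.07 ± 0.40) rising more in sWAT, while Ucp1 did not pass (−4.26 ± 1.01, adjusted p = 0.105). The count was 0 without any 1 of the 4 iBAT libraries, 0 without the female or male 30 °C sWAT library and 1190 or 3 without the female or male 10 °C sWAT library, and the 4 calls named ended with median-ratio scaling, without the filter on low values, and with the title prefix as a block. In the bat, 66 genes differed between those depots, 6 higher and 60 lower in iBAT, among them Fetub (3.71 ± 0.26), Tnnc1 (−6.96 ± 0.53), Tnni2 (−5.90 ± 0.59) and Tcap (−5.44 ± 0.63), with Ucp1 at 1.38 ± 0.46, adjusted p = 0.331. The count was 24 or 6 without the female or male 10 °C sWAT library, 34 without the female 30 °C iBAT library and 34 without the male 10 °C iBAT library. Added after the data were seen, the same contrast of bat aWAT with sWAT called 528 genes, 308 higher and 220 lower, with Ucp1 (9.96 ± 0.46) and Serhl (4.81 ± 0.52) rising more in aWAT and Tnnc1 (−6.91 ± 0.53) in sWAT. Without the 10 highest genes it called 235 higher and 292 lower. Its count was 137 with only the libraries of the groups compared, 1018 with the title prefix as a block, 147 or 172 without the female or male 30 °C sWAT library, 80 or 36 without the female or male 10 °C sWAT library, 82 without the female 30 °C aWAT library, 111 or 1020 without the female or male 10 °C aWAT library and 313 without the female or male 10 °C iBAT library. The contrast of aWAT with iBAT called 50, with Ucp1 (8.57 ± 0.46) rising more in aWAT. That count was 4 with median-ratio scaling, 7 without the filter on low values and 3 with only the libraries of the groups compared. It was 5 without the female or male 10 °C sWAT library, 6 or 29 without the female or male 30 °C aWAT library, 5 or 91 without the female or male 10 °C aWAT library, 4 or 2 without the female or male 30 °C iBAT library and 2 or 1 without the female or male 10 °C iBAT library.

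Between species, the cold effect in iBAT differed in 636 of 9400 genes, 492 higher and 144 lower in the bat. Ucp1 (−4.02 ± 0.79), Acot11 (−5.26 ± 0.35), Acsl5 (−4.69 ± 0.30) and Agpat2 (−4.44 ± 0.47) rose more in the mouse, while the change in the cold was higher in the bat for Pygb, a glycogen phosphorylase (4.45 ± 1.01), and for the uncertain Fabp7 (5.00 ± 0.51). The muscle gene Myl1 (3.37 ± 0.91) was called in that direction too, and warm mouse iBAT held abundant muscle transcripts. In sWAT it differed in 2479 genes, 1982 higher and 497 lower in the bat, with Ucp1 (−9.66 ± 0.79), Cox7a1 (−7.66 ± 0.41) and Cpt1b (−5.69 ± 0.38) rising more in the mouse and the antibody genes Ighg1 (7.85 ± 0.87) and Igkc (6.37 ± 1.41) falling in the mouse. The depot difference itself differed in 4545 genes, 3606 higher and 939 lower in the bat, with Ucp1 (7.79 ± 0.56) and Serhl (5.16 ± 0.31) higher and Ckm (−6.38 ± 1.69), Tnnc1 (−6.74 ± 0.83) and the uncertain Scd4 (−7.53 ± 1.12) lower. Medians of all genes were 0.21, 0.42 and 0.40, and scaling by median ratios called 276 higher and 308 lower in iBAT, 535 higher and 887 lower in sWAT and 1641 higher and 1872 lower between depots, quantile normalization 165 higher and 189 lower, 730 higher and 913 lower and 1690 higher and 1964 lower. The iBAT count was 193 or 241 without the female or male 30 °C mouse iBAT library, 188 or 276 without the female or male 10 °C mouse iBAT library, 221 or 391 without the female or male 30 °C bat iBAT library and 250 or 319 without the female or male 10 °C bat iBAT library. The sWAT count was 1315 or 1164 without the female or male 30 °C mouse sWAT library, 758 without the male 10 °C mouse sWAT library, 1269 without the male 30 °C bat sWAT library and 1350 or 1193 without the female or male 10 °C bat sWAT library, or 710 with only the libraries of the groups compared. The call of Ucp1 in iBAT ended with quantile normalization, and that of Myl1 with both scalings, without the filter and without the sex term.

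Sex changed little that could be detected. In the mouse limma called 0 genes, with 1425 at an unadjusted p under 0.05. The Y-linked Uty, chosen after its values were seen, was listed at 0 in the 4 female libraries and at 2.54 to 3.88 FPKM in the 4 male ones (log2 −2.08 ± 0.14 as fitted, adjusted p = 0.0865). X-linked Kdm6a, chosen likewise, was higher in females in 4 of 4 mouse pairs (0.75 ± 0.13, adjusted p = 0.368) and 6 of 6 bat pairs (0.66 ± 0.17, adjusted p = 0.19), both as fitted. Bat Uty, a close relative of Kdm6a and so uncertain, was above 0 in 4 of 6 female and 2 of 6 male libraries. Between bats of different sex limma called 8 genes, 4 higher and 4 lower in females, among them Gstm3, a glutathione transferase (1.42 ± 0.16), Usp43, a deubiquitinase (−2.41 ± 0.23), and Hspa2, a heat shock protein of the testis (−2.10 ± 0.25). The bat count was 0 without the female or male 30 °C sWAT library, 2 without the female or male 10 °C sWAT library, 0 without any 1 of the 4 aWAT libraries and 0 without any 1 of the 4 iBAT libraries. Calls ended with median-ratio scaling for Hspa2, with quantile normalization for Gstm3 and Hspa2, without the filter on low values for Gstm3, Usp43 and Hspa2 and with the title prefix as a block for Gstm3 and Hspa2.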

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

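The tests of a wrong label, of admixed iBAT, of another abdominal pad and of the share of lymphoid RNA, and the contrasts of the cold effect in bat aWAT with those in other depots, were chosen only after the result was seen. Changes in this part are as fitted, without the median of all genes taken off.

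These results drew attention because a contrast of cold effects or depots differed between groups by its own test. Between mouse iBAT and sWAT, 6 genes differed, with Acsl5 at 2.90 and Cox7a1 at −6.30. Between bat iBAT and sWAT it was 66 genes, with Fabp7, uncertain for its paralogs, at 4.63 and Tnnc1 at −7.13. In iBAT of bat against mouse it was 636 genes, with Fabp7 at 5.20, Acot11 at −5.05 and Ucp1 at −3.81. In sWAT it was 2479 genes, with Ighg1 at 8.28, from a fall in the mouse, and Ucp1 at −9.24. The depot difference of bat against mouse differed in 4545 genes, with Ucp1 at 8.18 and the uncertain Scd4 at −7.14. Bat aWAT differed from sWAT in its cold effect in 528 genes, with Ucp1 at 9.77 and Tnnc1 at −7.10, and from iBAT in 50, with Ucp1 at 8.55 and Prrt4 at −2.44.

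Thermogenic genes of iBAT rose in bat aWAT at 10 °C. Against a wrong label, 6 of 6 abdominal site markers were above the highest iBAT library in both cold aWAT libraries, as for Msln, at 10.7 FPKM or more against 0.344 or less. Against iBAT tissue mixed into the cold aWAT samples, Ucp1 would need shares of 0.814 and 0.333, while the interscapular markers Tbx15, Tbx22, Zic1 and Zic4 reached medians of 0.006 and 0.04 of the level that such shares need. Another thermogenic pad of the abdomen, taken at 10 °C, cannot be told apart, since 2 of 7 mesothelial genes differed and a pad with the same covering would show none. A response of the aWAT to cold is the explanation the design names, and it may hold, but it was not tested apart from that pad.

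Thermogenic genes rose and lymphocyte genes fell in mouse sWAT at 10 °C. A smaller share of lymphoid RNA, which would raise all other genes alike, could not be the whole cause: the TCA cycle list rose above the fibroblast list by 2.05 in the female pair and 2.73 in the male pair, more than the summed SDs of 1.01 and 1.71. The brown fat list against the general fat cell list did not part in this way, at −0.374 and 0.855 with list SDs of 0.909 to 2.677, so that this share stays open as a part of the change in those lists. Less lymph node tissue in the cold samples cannot be told apart. The female warm and male cold libraries had the most and least B lymphocyte signal (means 5.66 and 0.652). Between them, 9 genes of lymph node stroma had a median log2 ratio of 0.964 (SD 1.5). They ran from −0.304 (Ltbr) to 4.312 (Cxcr5), which are not of stroma alone, with Chst4 at 2.951 and Lyve1 at −0.115. Within 1 sex the stroma median changed by −0.678 (female) and −0.553 (male), and the B lymphocyte median by −1.314 and −5.12. The stroma median thus followed the loss of B cell genes poorly in the male pair. The loss of lymphocyte genes may therefore come from dissection or from the animals, and the cold effect on these cells remains untested.

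Skeletal muscle genes rose in bat sWAT at 10 °C. Muscle tissue in the cold samples is a candidate explanation, as 10 genes of muscle nuclei and the nerve junction had a median log2 difference of 0.465 in the female pair and 2.14 in the male pair, but most were under 1 FPKM, and the test leaves it open. In the female pair single members went both ways: Myf6 was called higher (adjusted p = 0.0407), at 0.103 and 0.0718 FPKM in the warm and 1.96 and 10.3 FPKM in the cold, while Chrna1 was at 10.6 and 3.05 FPKM in the warm and 1.01 and 4.17 FPKM in the cold. In the male pair none of the 10 was lower in the cold. Between the cold libraries 16 abundant muscle genes kept nearly 1 ratio (median log2 1.09, SD 0.366), as a common admixture would give. A change in the fat cells themselves is open, but this ratio does not favour it. Ckm was at 38.5 and 93.9 FPKM in the cold. How much muscle was dissected with the fat cannot be read from the labels.

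Other splits of the same libraries, fitted without the other factors, were compared with the real ones, taking the libraries as independent. If tissues of 1 title prefix came from the same animal, the 4 prefixes of a species would allow too few splits to exclude chance. With independent libraries, chance could be excluded for the depots, with 3914 genes in the mouse (highest other split 68), 4400 for bat iBAT against sWAT (1), 411 for iBAT against aWAT (317, the split by temperature) and 123 for aWAT against sWAT (2), each with 1 of 35 splits as large. For the mean cold effect in bats, 83 genes stood against a highest other of 1611, for a split with the iBAT libraries on 1 side. This points to tissue as the structure. Of 100 splits 2 were as large, but fits without tissue cannot decide chance. With the title prefix as a block the count of the full fit was 1010 against 2467. In the mouse, 36 genes for cold stood against 3914 for the split by depot, and 3 of 35 splits were as large, so that chance could not be excluded in these fits, which leave depot out and so say little about cold. For sex the mouse had 0 genes (highest other 3914), so that 35 of 35 splits were as large by necessity and nothing follows about chance. For bats (2 genes, highest other 83 for the split by temperature, 2 of 100) these fits without tissue and temperature cannot decide chance. The full fit called 1 gene with the block against 8.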

How the results depend on the processing

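Leaving out the 10 highest genes and the contrasts of the cold effect in bat aWAT with those in other depots were tests chosen only after the result was seen. The other alternatives were planned before the data were examined. Where leaving out a library left a group with 1 sample, that lone sample was assumed to vary like the other groups. No analysis paired by animal was run, because the labels do not name animals. Replicates 1 and 2 stand for sex, which the fit holds as a term. Whether tissues of the same title prefix come from the same animal is not said, and the prefix was tried as a random block. This block had a consensus correlation of −0.21 in mouse, 0.25 in bat and 0.20 over both, and was fitted to all comparisons but cold within 1 tissue. Read totals were unknown, so that counting error at low values could not be given. Alternatives for count tables were not run, since the values are FPKM.

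Counts of called genes that moved by over 1.5 times are grouped by setting, and the cause was not tested. Interactions are differences of cold effects between depots. With median-ratio scaling the count was 1429 for mouse iBAT cold, 2438 for mouse sWAT cold, 3149 for the mouse mean, 0 for the mouse interaction, 5 for bat sex, 1422 for sWAT between species and 4 for the interaction of bat aWAT and iBAT. Quantile normalization gave 824 for mouse iBAT cold, 2835 for mouse sWAT cold, 2859 for the mouse mean, 14 for the mouse interaction, 1 for mouse sex, 2 for bat sex, 354 for iBAT and 1643 for sWAT between species. A pseudocount of 0.1 gave 17 for the mouse interaction, 28 for the bat interaction of iBAT and sWAT and 4 for bat sex. Without the filter it was 0 for the mouse interaction, 0 for bat sex and 7 for the interaction of bat aWAT and iBAT, and without the sex term 10 for the mouse interaction. The title prefix as a block gave 0 for the mouse interaction, 1 for mouse sex, 1 for bat sex, 1010 for the bat mean and 1018 for the interaction of bat aWAT and sWAT. With only the libraries of the groups compared the count was 3338 for mouse iBAT cold, 2110 for mouse sWAT cold, 64 for bat sWAT cold, 1144 for bat aWAT cold, 41 for the bat interaction of iBAT and sWAT, 137 for that of aWAT and sWAT, 3 for that of aWAT and iBAT and 710 for sWAT between species, in fits with fewer samples. Leaving out the 10 highest genes gave 4 for bat sex. Robust eBayes moved none of these counts by that much. Of 122 tests of lists for the cold, camera called 45, camera with an estimated correlation 0 and fry 23, and of 97 for the depots 49, 3 and 53.

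Leaving out 1 library gave counts from 2 to 2711 for mouse iBAT cold, 28 to 4338 for mouse sWAT cold, 4 to 387 for bat iBAT cold, 10 to 118 for bat sWAT cold and 426 to 2175 for bat aWAT cold. It gave 2501 to 5806 for the mouse mean, 1375 to 2854 for the bat mean, 6081 to 7267 for the mouse depots, 4352 to 5610 for bat iBAT against sWAT, 1465 to 3041 for iBAT against aWAT and 1017 to 1958 for aWAT against sWAT. For cold effects it gave 0 to 1190 for the mouse interaction, 6 to 63 for bat iBAT against sWAT, 36 to 1020 for aWAT against sWAT, 1 to 91 for aWAT against iBAT, 188 to 733 for iBAT and 758 to 2757 for sWAT between species. For the depot difference between species it gave 3829 to 4719, for mouse sex 0 to 2 and for bat sex 0 to 2.

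No named gene turned its direction in any of these settings. A named gene lost its call, or gained one, in the same direction 10 and 1 times with median-ratio scaling, 13 and 0 times with quantile normalization, 21 and 0 without the filter, and 12 and 0 without the sex term. It was 4 and 0 times with a pseudocount of 0.1, 12 and 1 with only the libraries of the groups compared, 6 and 0 with the block, 0 and 0 with robust eBayes, 1 and 0 without the 10 highest genes, and 419 and 3 over all libraries left out 1 at a time.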

Other observations

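The genes in this part were chosen after their values were seen, and no tests were run for this part. Those present in the fits were among the genes of the comparison of female and male mice, which called 0. Female mouse sWAT held genes of the mammary gland, whose ducts run through this fat pad in females. Epcam, an adhesion protein of epithelia, was at 64.7 FPKM in the warm and 33.1 FPKM in the cold female library, and at 1.03 and 0.051 FPKM in the male ones. Ltf, the lactoferrin of milk and secretions, was at 329 and 148 FPKM in females against 0.421 and 0.0186 FPKM in males, and Krt14, a keratin of basal epithelium, at 20.9 and 5.48 against 0.049 and 0 FPKM. In bat sWAT, Epcam was at 1.37 and 0.538 FPKM in the warm and 4.58 and 2.12 FPKM in the cold.

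Mitochondrial transcripts took unlike shares of the depots. Together, mt-Co2 and mt-Nd2, which the mitochondrial genome encodes, made up 24.5% of the summed FPKM in mouse iBAT and 9.2% in mouse sWAT. The next most abundant mouse genes took under 1% each.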
